A study of Mus musculus with 677 samples.

How the data were processed

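The series holds 677 single-cell libraries from the intestinal epithelium of C57BL/6 mice, 335 from WT and 342 from Atg16l2 KO animals. Per the labels, libraries were made with SMART-Seq2; the labels also name a droplet kit of 10X Genomics, and to which cells, if any, that kit applies was not analysed here. Per the submitters' processing notes, reads were aligned with Bowtie and TopHat and expression was estimated with RSEM, for which no versions and no genome build are given in the sources used here. The authors deposited a table of TPM values from RSEM, with 23420 genes and a column for each cell, and all columns were matched to a library (0 left over). The sums of the cells ran from 999999.17 to 1000000.78 TPM, so the table keeps no sequencing depth, and raw reads were not used here. No mitochondrially encoded gene is listed (0 of 13 of that list), so a filter on mitochondrial reads was not possible.

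Run, animal code and cell type were taken from the library titles. The code M1 or M2 was read as an animal, giving WT M1 (168 cells), WT M2 (167), KO M1 (172) and KO M2 (170); the labels do not spell this out, and whether M1 of run 1 and M1 of run 2 are the same animal is not stated. No cell was removed in the main analysis, no doublet caller was run, and the authors' 9 cell types were kept as labelled. Groups, comparisons, gene lists, markers, alternatives and the rule for naming genes were fixed before the data were examined, and alternatives added later are named as such.

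For each animal and cell type the mean TPM over cells was taken and transformed as log2(TPM + 1). Cell types with at least 10 cells in every animal were tested (6 of 9), each alone and as an unweighted average of the 6. Genes were kept at a mean of at least 10 TPM and with more than 0 TPM in at least 10% of cells. KO and WT were compared with limma (lmFit, then eBayes with an intensity trend, residual df 2), two-sided, with Benjamini-Hochberg adjustment over all kept genes at 0.05. The average is of log2 values, so it can differ in sign from a difference of mean TPM. A moderated F test in limma asked whether the difference varied over the 6 types (24 values, residual df 10). Gene lists with at least 5 kept members were tested with limma's camera, with the preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists of a comparison. Cell type shares were compared by exact permutation of the 3 distinct splits of 4 animals, for which the smallest two-sided p is 0.333. Intervals on shares of cells are exact binomial 95% intervals; where no cell was positive, 3 divided by the number of cells is given as the share that is still allowed.

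The lists were autophagy core, lysosome, unfolded protein response, interferon response, MHC class I, MHC class II, antimicrobial, epithelial inflammation, stem cell, proliferation, enterocyte absorption, proximal and distal small intestine, goblet secretion, oxidative phosphorylation, glycolysis, cholesterol synthesis, fatty acid oxidation and PPARA targets, NRF2 targets, p53 targets and cell death, immediate early and dissociation stress, ribosomal protein, and genes near Atg16l2 with substrain checks. Lists of T cell, B and plasma cell, myeloid, and stromal, endothelial and red cell markers and of sex-linked transcripts were not tested. They were summed in TPM per cell and averaged over all cells of each animal. Named genes were, for every comparison, Atg16l2, Atg16l1 and Nnt (from the fit without the filter on low values), the passing genes, and otherwise those with the smallest unadjusted p among genes in which both KO animals lay beyond both WT animals, with all 6 types of the same sign for the average; up to 8 per direction were named for the average and up to 4 per type. Genes known only by a Gm or Rik symbol were counted but not ranked. List members named are those with the smallest p.

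Alternatives fixed beforehand were pseudocounts of 0.1 and 10, no filter on low values, a filter of 50 TPM, log values averaged over cells, quantile normalization, TPM rescaled without 92 ribosomal protein genes, each of the 2 runs alone, the 8 combinations of run and animal as units with run as a covariate (with duplicateCorrelation or as 8 animals), the replicate number as a block, a cell filter of 2000 genes, eBayes without trend, and leaving out each animal. Those added after the data were seen were a cell filter of 5000 genes, a trend with transcript length removed per profile (lowess span 0.4, longest annotated transcript), the highest cell of each animal and type left out, cells of other types with over 3% of TPM in 9 Paneth markers left out, the run 1 cells of KO M2 left out, a crossed pairing of animals, and Goblet cells with over 3% Paneth and under 1% Goblet marker TPM counted as Paneth.

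The procedure was tested on simulated data made by drawing cells of each type with replacement and changing known genes in the KO cells. Cells were drawn from all animals and both runs pooled, so the simulated data held no differences between animals or runs. The rates that follow do not cover such differences. Of 100 genes changed 4-fold, 85% were recovered in the average, 66% in Stem, 94% in TA, 96% in Enterocyte.prog.early, 66% in Enterocyte.prog.late, 35% in Enterocyte and 65% in Goblet cells, and 39% in the interaction test. In the same order, calls among unchanged genes numbered 8, 16, 12, 3, 0, 1, 18 and 15. In 50 draws without any change the average called a median of 0 genes (at most 9), and camera called a median of 4 lists with the preset and 0 with an estimated correlation. A glycolysis list shifted by 0.5 on the log2 scale was called with the preset correlation (camera adjusted p = 8.74e-36) and not with an estimated one (0.123). In such draws the preset camera test was thus liberal and the estimated one conservative at 2 animals per group. Analyses ran in R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8), and Python 3.11.15 with matplotlib 3.10.9.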

Results

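The series profiled single epithelial cells of the mouse intestine, all from C57BL/6 mice, by SMART-Seq2, a plate-based method that sequences full-length cDNA of one cell per library. The cells came from wild-type (WT) mice and from mice carrying a knockout of Atg16l2 (KO), a homologue of the autophagy gene Atg16l1. The comparison asked what loss of Atg16l2 does to the cells of this epithelium. The cell names carried a run code (1 or 2), a code M1 or M2 within each genotype and 1 of 9 cell types annotated by the authors. The M codes were read as animals, which gave 2 animals per genotype (WT M1, WT M2, KO M1 and KO M2), each with 80 to 87 cells in each run. The deposited values were TPM, a measure of relative transcript abundance with the same sum in every cell, so the depth of each cell is unknown. The median number of genes above 0 TPM was 6042 in WT cells and 6170 in KO cells, with a range of 3662 to 10472 over all cells. Run 1 cells had more genes above 0 TPM (medians of 6247 to 6615 per animal) than run 2 cells (5460.5 to 5878). P-values here measure the spread between 2 animals per genotype, and intervals on shares of cells cover counting error only.

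The targeted gene was examined first. Atg16l2 was above 0 TPM in 38 WT cells, or 11.3% (exact 95% binomial interval 8.15 to 15.2%), with 11.9% in WT M1 and 10.8% in WT M2. It was listed at 0 in every KO cell, which allows a share of up to 0.877%. Averaged over 6 cell types, its level was 5.90 ± 0.94 TPM in WT (SD, n = 2 animals) and listed at 0 in both KO animals, within each run as well. In WT, Atg16l2 was seen in 11 of 49 Stem cells (22.4%, exact interval 11.8 to 36.6%) and 16 of 85 TA cells (18.8%, exact interval 11.2 to 28.8%). It was seen in 2 of 64 Enterocyte.prog.early cells, 1 of 43 Enterocyte.prog.late cells and 0 of 29 Enterocyte cells, the last of which allows a share of up to 10.3%. Atg16l2 lay below the filter of 10 TPM. limma fitted without the filter on low values gave a difference of -1.72 on the log2(TPM + 1) scale (SE 0.14, Benjamini-Hochberg adjusted p = 0.854), with both KO animals below both WT animals. With the 8 combinations of run and animal as units the adjusted p was 0.0175, for a difference of -1.59. Atg16l1, the scaffold of the LC3 conjugation machinery, was above 0 TPM in 47.8% of WT cells and 51.8% of KO cells. Atg16l1 stood at 19.4 ± 2.22 TPM in WT and 18.8 ± 1.46 TPM in KO (SD, n = 2 each), a log2 difference of -0.11 in the same fit without the filter (SE 0.15, limma Benjamini-Hochberg adjusted p = 0.887). That difference was 0.18 in run 1 cells and -0.61 in run 2 cells. Nnt, a mitochondrial transhydrogenase gene that differs between C57BL/6 substrains, differed by 0.03 in that fit (SE 0.15; -0.20 in run 1 and 0.19 in run 2), with 28.5 TPM in both genotypes.

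**Figure D1:**
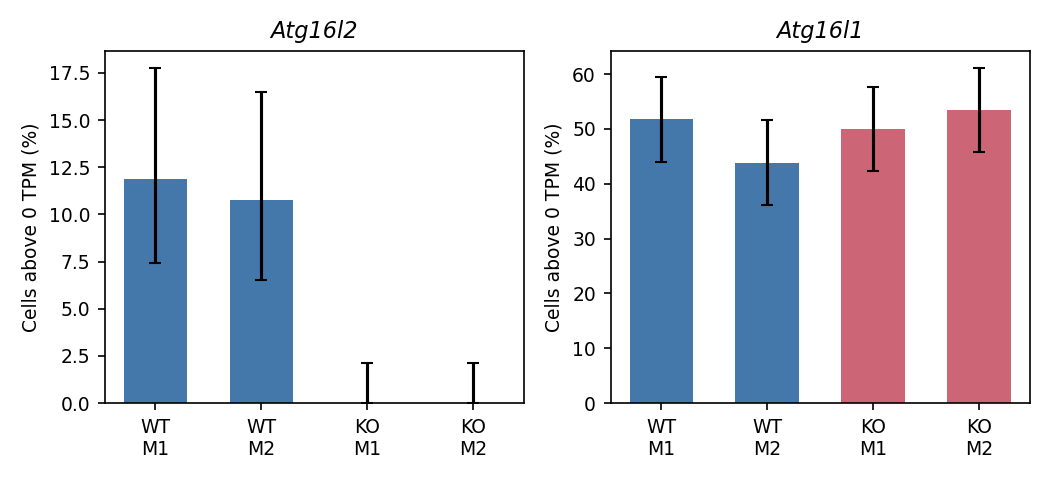
Share of each animal's cells above 0 TPM (vertical axis, %) for Atg16l2 (left) and Atg16l1 (right) in WT M1, WT M2, KO M1 and KO M2, with exact 95% binomial intervals as error bars. Atg16l2 was seen in 11.9% and 10.8% of the cells of the WT animals and in 0% of those of the KO animals.

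The next comparison asked whether loss of Atg16l2 shifted the cell types that make up the epithelium. Cells annotated Paneth, the antimicrobial secretory cells of the crypt base, made up 4.48 ± 1.29% of WT cells and 2.05 ± 0.40% of KO cells (SD, n = 2 animals each; 15 and 7 cells). Enterocyte.prog.early cells made up 19.1 ± 0.92% of WT and 22.8 ± 2.29% of KO cells. In these types alone among the 9 did both KO animals lie on 1 side of both WT animals. The Paneth share differed by -2.44 percentage points (-2.99 in run 1 and -1.82 in run 2), and the Enterocyte.prog.early share by 3.69 points (5.51 and 1.81). Each had a two-sided exact permutation p of 0.333, the smallest that 2 against 2 animals allow. The Paneth separation depended on the annotation. With 3 KO M1 Goblet cells of Paneth marker profile counted as Paneth, an alternative added after the values were seen, the share was 4.07% in KO M1 and 1.76% in KO M2 against 3.57% and 5.39% in WT (exact permutation p = 0.667). The other types overlapped between genotypes: Stem (14.6 ± 3.86% in WT, 13.7 ± 4.44% in KO), TA (25.4 ± 4.54%, 26.3 ± 1.44%), Enterocyte.prog.late (12.8 ± 0.37%, 9.38 ± 5.04%), Enterocyte (8.65 ± 2.92%, 8.49 ± 2.14%) and Goblet (10.5 ± 3.84%, 10.2 ± 2.81%). Enteroendocrine cells, which secrete gut hormones, made up 3.58 ± 2.52% in WT and 5.87 ± 4.18% in KO (12 and 20 cells), and Tuft cells, the chemosensory type, 0.896% and 1.17% (3 and 4 cells). No share passed the test in these 9 comparisons (Benjamini-Hochberg adjusted exact permutation p = 1 for each). The whole composition differed by a total variation distance of 7.20% between genotypes (exact permutation p = 0.667), against 14.6% between the WT animals and 16.1% between the KO animals.

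**Figure D2:**
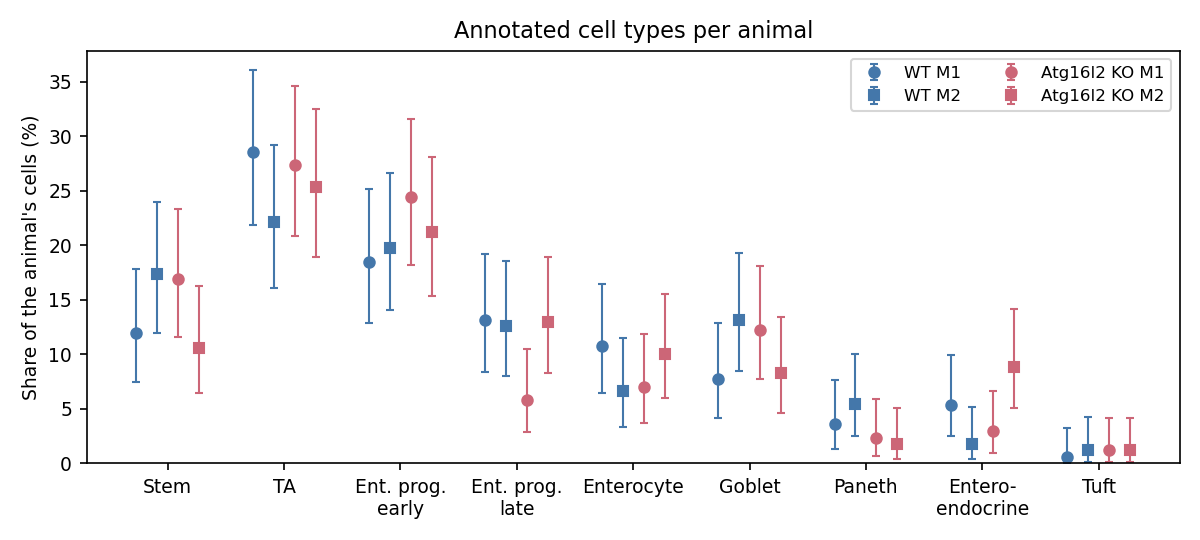
Share of each animal's cells (vertical axis, %) in the 9 annotated cell types, with circles for M1, squares for M2, blue for WT, red for KO and exact 95% binomial intervals as bars. The Paneth share averaged 4.48% in WT and 2.05% in KO as annotated, and 2.92% in KO with 3 Goblet cells of Paneth profile counted as Paneth.

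Across the average of 6 cell types (Stem, TA, Enterocyte.prog.early, Enterocyte.prog.late, Enterocyte and Goblet), no single gene passed the test. The genes highest in KO by their unadjusted p included products of Paneth cells: Lyz1, which encodes lysozyme (105.8 and 181.9 TPM in WT, 1019 and 252.7 in KO; log2 difference 2.05, SE 0.32), and Ang4, an antimicrobial ribonuclease (1.92, SE 0.28). For Ang4 the mean TPM was the lower one in KO (92.7 ± 98.6 in WT, 85.7 ± 37.5 in KO; SD, n = 2), because the log2 values were averaged over types. The other higher genes were Gstm3, a glutathione transferase (0.76), the transferrin receptor Tfrc (0.62), the matrix protease Mmp14 (1.03), the kinase Stk11 (0.88), the mitotic regulator Cdc20 (0.74) and the drug efflux pump Abcb1a (0.80). Among the lower genes, Rps27, a protein of the small ribosomal subunit, differed most (640 and 1037 TPM in WT, 282.3 and 118.6 in KO; -2.86, SE 0.34). Rn4.5s (-1.12), the mitochondrial protein genes Romo1 (-0.80) and Ndufa3 (-0.76), Dpm3 (-0.96), Bola2 (-0.70) and Wdyhv1 (-0.78) were also lower. Both KO animals lay beyond both WT animals for each of these genes, a pattern that 39.1% of the tested genes showed and that chance gives for 33.3%. The higher genes were also higher in KO within each run (0.29 to 2.09 in run 1, 0.35 to 2.69 in run 2), whereas the lower genes differed by -4.98 to -0.81 in run 1. In run 2 the lower genes differed by -0.42 to 0.32, and Rps27 and Bola2 lay above WT. limma called 0 of 6714 genes after Benjamini-Hochberg adjustment (smallest adjusted p = 0.219, for Rps27), with 510 genes at an unadjusted p under 0.05 against 335.7 by chance. The gene-wise differences of run 1 and run 2 were almost unrelated across genes, which are not independent replicates (Pearson r = 0.0657, Spearman rho = 0.0412, the same sign in 50.1% of genes). limma called 5 genes in run 2 cells alone, 19 without KO M2 and 1 with the 8 combinations of run and animal as units.

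On the same average 7 of 23 gene lists fixed beforehand were called, 5 higher and 2 lower in KO. Member counts are of genes kept by the filter on low values. The MHC class II list, which presents antigen to CD4 T cells, kept 7 of 8 genes. All 7 were higher in KO, with a median log2 difference of 0.77 (limma camera, preset correlation, Benjamini-Hochberg adjusted p = 0.000118). Among them, H2-Aa stood at 265.5 and 105.4 TPM in WT and 444 and 327.1 TPM in KO (1.25, SE 0.39), and the invariant chain gene Cd74 differed by 0.79 (SE 0.31). None of the 7 passed over all genes and 0 passed adjusted over the list alone, and the adjusted p was 0.583 with an estimated correlation. The MHC class II median was 1.34 in run 1 cells and -0.05 in run 2 cells, and 0.065 once the run 1 cells of KO M2 were left out. Marker sums of other cell types were taken over all cells of each animal, including the types that were not tested. T cell markers summed to 8.02 and 15.8 TPM in WT and 17.4 and 15.995 TPM in KO. B cell markers summed to 4.44 and 5.87 against 2.77 and 4.92, and myeloid markers to 9.05 and 13.1 against 8.40 and 21.5. Markers of stroma, endothelium and red cells summed to 77.6 and 47.1 TPM in WT and 163.6 and 115.5 TPM in KO, and sex-linked transcripts to 62.2 and 64.1 against 83.8 and 87.8.

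The antimicrobial list was made of secreted lectins, defensins, lysozyme and other host defence genes. Of its 36 genes the filter kept 25, and 20 of these were higher in KO. The list median was 1.62 (0.82 in run 1 and 1.76 in run 2, camera adjusted p = 6.85e-10). With log values averaged over cells the list was not called. The lectin gene Itln1 differed by 1.62 (SE 0.23) and the alpha-defensin gene Defa24 by 1.96 (SE 0.39). Over all genes 0 of the 25 passed, 16 higher and 2 lower passed adjusted over the list alone, and the adjusted p was 0.583 with an estimated correlation. The list holds 8 of the 9 Paneth markers, and its median was 0.44 when 9 cells of other annotated types that carried Paneth transcripts were left out. Alpha-defensins are near-identical copies, so the level of each of them is uncertain. Smaller shifts were called for the stem cell list (14 of 18 members higher, median 0.31; 0.26 in run 1 and 0.24 in run 2; camera adjusted p = 0.00422) and the proliferation list (27 of 38 higher, median 0.19; 0.35 and -0.28; camera adjusted p = 0.00197). The proliferation list was not called without the run 1 cells of KO M2 (median 0.023, camera adjusted p = 0.410). On the average the stem cell list was not called with log values averaged over cells, with at least 50 TPM or with the highest cell left out. It was called in no single type, and in Stem cells 10 members were higher and 12 lower (median -0.044, with 0.22 in run 1 and -0.11 in run 2). There its camera adjusted p was 0.525 with the preset and 0.827 with an estimated correlation, with 0 members over all genes and 0 adjusted over the list alone. In run 2 Stem cells alone, with the low-value filter applied within the run, the stem cell list was called lower in KO (median -0.15, camera adjusted p = 0.0330). Among the members of both lists on the average, the stem cell transcription factor Ascl2 differed by 0.75 (SE 0.36) and the matrix protein gene Smoc2 by 0.35 (SE 0.13). The mitotic ubiquitin-conjugating enzyme gene Ube2c differed by 0.68 (SE 0.16). Fatty acid oxidation and PPARA targets were higher for 16 of 18 members (median 0.13; 0.37 and 0.16; camera adjusted p = 0.00271), with the transcription factor gene Creb3l3 at 0.67 (SE 0.25). For each of these 3 lists 0 members passed over all genes and 0 adjusted over the list alone. The call of each of the 3 ended in at least 1 case when 1 animal was left out. With an estimated correlation the adjusted p was 0.583 for the stem cell and proliferation lists and 0.642 for fatty acid oxidation.

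The lists called lower in KO were oxidative phosphorylation (43 of 49 members lower, median -0.30, camera adjusted p = 2.49e-13) and ribosomal protein (35 of 40 lower, median -0.25, camera adjusted p = 7.54e-11). Ndufs6, a subunit of respiratory complex I, differed by -0.59 (SE 0.16), Uqcr11, of complex III, by -0.68 (SE 0.17), and the ribosomal protein gene Rpl38 by -0.65 (SE 0.17). Over all genes 0 members of either list passed, and adjusted over the list alone 0 oxidative phosphorylation genes and 1 ribosomal protein gene, Rps27, passed. With an estimated correlation the adjusted p was 0.583 and 0.642. The medians were -0.64 and -0.70 in run 1 cells and -0.02 and 0.10 in run 2 cells. By animal, the run 1 means of the oxidative phosphorylation list were 9.60 and 9.73 in WT and 9.49 and 8.67 in KO. Those of the ribosomal protein list were 11.1155 and 11.1056 in WT and 10.83 and 9.91 in KO, with KO M2 the lowest in each. With the run 1 cells of KO M2 left out the medians were -0.21 and -0.10, and both lists were still called (camera adjusted p = 5.23e-12 and 0.0477). With the trend with transcript length removed they were -0.079 and -0.059, and both were still called (camera adjusted p = 2.42e-06 and 0.00225). The run 1 profile of KO M2 stood apart from the other run 1 profiles on the first principal component (21.3, against -17.0, -23.1 and -18.0). Ribosomal protein genes have many near-identical pseudogenes, so their levels are uncertain.

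The 16 lists that were not called included the autophagy core list, in which 10 of 30 members were higher and 20 lower (median -0.04; 0.03 in run 1 and -0.15 in run 2; camera adjusted p = 0.628), with the phosphoinositide-binding gene Wdr45b at -0.29 (SE 0.15). The other medians were 0.03 for lysosome, -0.07 for the unfolded protein response, -0.09 for interferon response, 0.03 for MHC class I, -0.06 for epithelial inflammation, 0.0017 for enterocyte absorption, 0.34 for proximal and 0.01 for distal small intestine, 0.05 for goblet secretion, 0.03 for glycolysis, 0.0073 for cholesterol synthesis, 0.06 for NRF2 targets, -0.0027 for p53 targets and cell death, -0.14 for immediate early and dissociation stress, and 0.08 for genes near Atg16l2. Their camera adjusted p ran from 0.0518 to 0.969 with the preset correlation. No member of these lists passed over all genes. Adjusted over the list alone, 2 higher and 1 lower genes of the proximal small intestine list and 3 higher and 1 lower NRF2 targets passed, among them Aldh1a1, which makes retinoic acid (1.32, SE 0.20). For the lysosome, MHC class I, distal small intestine, cholesterol synthesis and p53 lists the median and the direction of the camera test had opposite signs. With the estimated correlation limma's camera called 0 of 23 lists (smallest adjusted p = 0.583). In 50 simulated draws of unchanged cells the preset correlation called a median of 4 lists (range 1 to 12), and 8 of the 50 called 7 or more. The draws pooled all animals and runs, so they cannot give the rate of false calls where these differ.

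**Figure D3:**
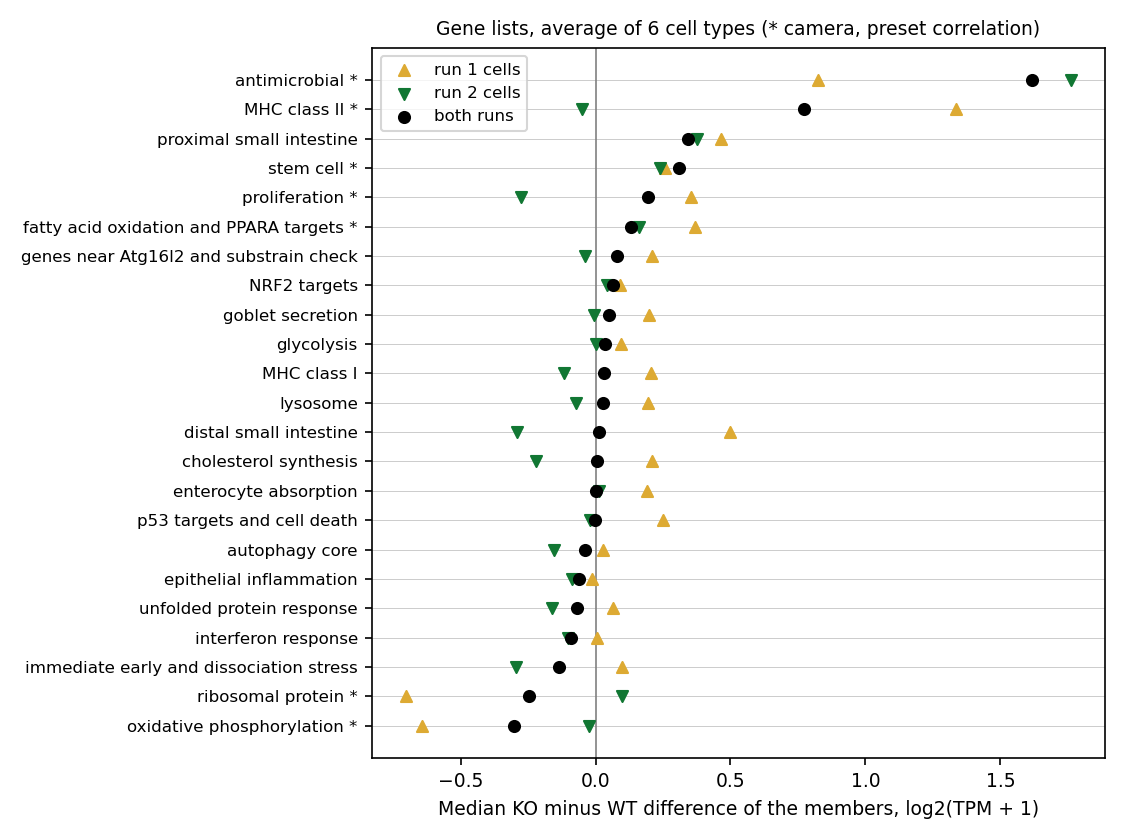
Median KO minus WT difference of the members of each of the 23 gene lists (horizontal axis, log2(TPM + 1) scale; vertical axis, lists), averaged over 6 cell types, for both runs (black circles), run 1 cells (upward triangles) and run 2 cells (downward triangles). An asterisk marks the 7 lists called by camera with the preset correlation; MHC class II lay at 1.34 in run 1 and -0.05 in run 2.

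In TA cells, the annotated type with the most cells, KO animals had more H2-Aa, an MHC class II chain gene (225.7 and 131.5 TPM in WT, 704 and 471 in KO), and less of the zinc-binding metallothionein gene Mt2 (128.1 and 91.8 TPM in WT, 25.5 and 41.1 in KO). H2-Aa rose by 1.73 (SE 0.26, limma Benjamini-Hochberg adjusted p = 0.0372) and Mt2 fell by 1.71 (SE 0.26, limma Benjamini-Hochberg adjusted p = 0.0391), in both KO animals against both WT animals. Mt2 was lower in both runs (-1.70 and -1.66), while H2-Aa differed by 2.04 in run 1 and 0.62 in run 2. The other TA genes past the threshold, Rps27 (-1.96, SE 0.29) and the histone gene Hist1h2ap (-1.53, SE 0.23), each had a limma adjusted p of 0.0372, with both KO animals below both WT animals. They were lower in run 1 (-2.87 and -2.73) and higher in run 2 (4.11 and 2.07). Both belong to families of near-identical copies. The TA MHC class II list was higher for 6 of 6 members (median 1.06; 1.41 in run 1 and 0.38 in run 2; camera adjusted p = 3.80e-08). Of these, 1 passed over all genes and 5 adjusted over the list alone, and the adjusted p was 0.881 with an estimated correlation. H2-Ab1 differed by 1.29 (SE 0.32). TA MHC class I genes were higher for 7 of 8 members (median 0.40; 0.33 and 0.25; 0 over all genes, 1 adjusted over the list alone), and the antimicrobial list was lower for 15 of 21 (median -0.37; -0.18 and -0.24; 0 over all genes, 2 lower adjusted over the list alone). Their camera adjusted p were 0.00329 and 0.000108 with the preset and 0.881 with an estimated correlation. The TA lists with the smallest p were oxidative phosphorylation (41 of 49 members lower, median -0.37; -0.62 in run 1 and -0.017 in run 2; camera adjusted p = 3.44e-16; 0 over all genes, 0 adjusted over the list alone) and ribosomal protein (38 of 40 lower, median -0.35; -0.64 and 0.10; camera adjusted p = 8.53e-16; 1 over all genes, Rps27, and 1 adjusted over the list alone). The adjusted p was 0.881 for both with an estimated correlation, and the medians were -0.24 and -0.11 without the run 1 cells of KO M2. In run 2 cells alone the TA ribosomal protein list was called higher in KO (median 0.10, camera adjusted p = 0.000842). Among TA genes that did not pass, Cd74 (1.04), Pggt1b (1.22), Wrb (1.39) and Cyp2e1 (1.27) were the next higher ones (0.85 to 1.39 in run 1, 0.27 to 2.12 in run 2). Hist1h2ao (-1.17), Ifi27l1 (-2.41), Dpm3 (-1.19) and Slirp (-0.91) were the next lower ones (-3.34 to -1.28 and -1.81 to 0.40). limma called 4 of 6791 TA genes (541 at an unadjusted p under 0.05), 2 in run 1 cells, 0 in run 2 cells, 0 without WT M2, 17 without KO M2, 9 without WT M1 and 2.3e+02 without KO M1. With the animals regrouped as WT M1 and KO M1 against WT M2 and KO M2, limma called 3 TA genes. Without the run 1 cells of KO M2 the TA MHC class II median was 0.20, the MHC class I median 0.052 and H2-Aa differed by 0.60, and neither list was called (camera adjusted p = 0.524 and 0.314). The call of the TA MHC class I list also ended without WT M1, WT M2 or KO M1, and that of the TA antimicrobial list without KO M1 (median -0.075, camera adjusted p = 0.489).

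Enterocyte.prog.early cells showed the same list with a larger median: 6 of 6 MHC class II members were higher (median 1.40; 1.84 in run 1 and 0.47 in run 2; camera adjusted p = 1.20e-08). H2-Aa stood at 166.95 and 38.04 TPM in WT and 418 and 340 TPM in KO (2.22, SE 0.55). Over all genes 0 of the 6 passed and 6 passed adjusted over the list alone, with an adjusted p of 0.758 with an estimated correlation. Without the run 1 cells of KO M2 the median was 0.51 and the list was not called (camera adjusted p = 0.192). The other lists called higher were enterocyte absorption (22 of 26 members, median 0.28, with 0.50 in run 1 and -0.031 in run 2) and fatty acid oxidation (15 of 16, 0.22, with 0.36 and 0.079). So were antimicrobial (18 of 22, 0.61, with -0.088 and 1.07, and -0.079 without cells that carried Paneth transcripts) and MHC class I (8 of 9, 0.27, with 0.55 and 0.027, and 0.0010 without the run 1 cells of KO M2). Their camera adjusted p were 6.06e-05, 0.0278, 0.0453 and 0.0466. Called lower were oxidative phosphorylation (41 of 49 members, median -0.29, with -0.67 in run 1 and 0.0089 in run 2, camera adjusted p = 2.19e-13) and ribosomal protein (34 of 40, -0.23, with -0.76 and 0.16, camera adjusted p = 1.37e-10). The ribosomal protein list was not called without the run 1 cells of KO M2 (median -0.074, camera adjusted p = 0.114). In these 6 lists 0 members passed over all genes. Adjusted over the list alone 4 absorption genes and 0 of the others passed, and the adjusted p ran from 0.758 to 0.854 with an estimated correlation. Phgdh (1.90), the retinol carrier gene Rbp2 (0.90) and the fatty acid carrier gene Fabp1 (1.10) were among the higher genes with the smallest p, and Mt2 (-1.31), Hist1h2ao (-1.37), Hist1h2ag (-1.90) and Rps27 (-1.44) among the lower ones. The higher ones differed by 0.79 to 2.25 in run 1 and 1.08 to 2.09 in run 2, the lower ones by -2.72 to -1.96 and -1.44 to 0.95. limma with Benjamini-Hochberg adjustment called 0 of 6565 genes (5.51% of them at an unadjusted p under 0.05, smallest adjusted p = 0.737), and 6 without WT M1 or without KO M2. In Stem cells limma also called 0 of 6764 genes (5.50% of them at an unadjusted p under 0.05, smallest Benjamini-Hochberg adjusted p = 0.790), with 1 in run 2 cells and 13 without KO M1. Of 22 lists tested in Stem cells, camera called 7. Higher in KO were the antimicrobial list (17 of 20 members, median 0.71, with -0.0080 in run 1 and 1.22 in run 2), fatty acid oxidation (14 of 17, 0.25, with 0.41 and 0.26), proliferation (21 of 28, 0.25, with 0.20 and 0.17) and MHC class II (7 of 7, 0.35, with 1.16 and -0.039, and -0.097 without the run 1 cells of KO M2). Their camera adjusted p were 3.96e-07, 0.00438, 0.00768 and 0.0415. With the highest cell of each animal left out the Stem antimicrobial list was not called (median 0.27, camera adjusted p = 0.665). The Stem proliferation median was 0.0030 without WT M1 and 0.016 without KO M1, and the list was called in neither case (camera adjusted p = 0.866 and 0.715). Lower were the ribosomal protein list (36 of 40 members, median -0.21, with -0.70 in run 1 and 0.024 in run 2), oxidative phosphorylation (40 of 49, -0.25, with -0.87 and 0.091) and epithelial inflammation (10 of 14, -0.32, with -0.54 and -0.14). Their camera adjusted p were 8.37e-12, 2.80e-08 and 0.0415. No member of these lists passed over all genes, 2 higher antimicrobial and 2 lower ribosomal protein genes passed adjusted over the list alone, and the adjusted p was 0.827 for each with an estimated correlation. Stem cell values were highest in KO, by unadjusted p, for Dynlt1a (2.06), Defa22 (1.52), Dcbld1 (1.98) and the histone chaperone gene Asf1b (1.79), and lowest for Rps27 (-2.59), Gpr30 (-2.16), Rn4.5s (-1.73) and the vacuolar ATPase gene Atp6v0c (-1.11). Within runs these Stem genes differed by 0.45 to 3.48 and 1.64 to 2.67 on the higher side, and by -6.63 to -1.95 and -2.05 to 2.43 on the lower side.

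Enterocyte.prog.late cells of KO animals carried more Aldh1a1, a retinaldehyde dehydrogenase gene (16.02 and 18.2 TPM in WT, 90.3 and 79.8 in KO), and more transcripts of Paneth products. Aldh1a1 rose by 2.25 (SE 0.34; 2.75 in run 1 and 1.96 in run 2), Itln1 by 4.98 (SE 0.73; 4.03 and 3.18), and the alpha-defensin genes Defa17 by 6.72 (SE 0.96; 2.95 and 6.04) and Defa20 by 3.88 (SE 0.54; 2.37 and 3.17). Gm14851, an alpha-defensin-related gene that fell outside the rule for named genes and was chosen after its values were seen, rose by 5.81 (SE 0.76; 3.94 and 5.42). These 5 of 6120 genes, each higher in both KO animals than in both WT animals, had a limma Benjamini-Hochberg adjusted p of 0.0454, and 5.605% of the genes had an unadjusted p under 0.05. A single cell held 98.5% of the summed Paneth marker TPM in KO M2 and a single cell 89.9% in KO M1. Higher without passing were Adh1, an alcohol dehydrogenase gene (302.6 and 298.3 TPM in WT, 775 and 767 in KO; 1.36, SE 0.22; limma Benjamini-Hochberg adjusted p = 0.0595), Ces2c, a carboxylesterase gene (1.52), Defa24 (5.46) and Defa5 (4.91). These 4 genes differed by 1.44 to 3.05 in run 1 and 0.87 to 6.27 in run 2. The lower ones were Rps27 (-6.62), Mto1 (-2.38), Hist1h2ao (-3.68) and Ptpmt1 (-1.12), at -6.98 to -1.02 in run 1 and -6.94 to 0.65 in run 2. The antimicrobial list was higher for 17 of 22 members (median 2.94; 1.17 and 1.94; camera adjusted p = 2.37e-21), 4 over all genes and 14 adjusted over the list alone, with an adjusted p of 0.541 with an estimated correlation. Proximal small intestine genes were higher for 7 of 10 members (median 0.53; 0.47 and 0.50; camera adjusted p = 0.000544; 0 over all genes, 3 adjusted over the list alone; adjusted p of 0.541 with an estimated correlation), led by Creb3l3 (18.02 and 32.6 TPM in WT, 89.3 and 89.1 in KO; 1.83, SE 0.36). NRF2 targets were higher for 10 of 17 (median 0.27; 0.29 and 0.02; camera adjusted p = 0.0113; 1 over all genes, 3 adjusted over the list alone; adjusted p of 0.561 with an estimated correlation), among them the glutathione transferase gene Gstm1 (1.35, SE 0.30). Enterocyte absorption genes were higher for 22 of 29 (median 0.30; 0.60 and -0.09; camera adjusted p = 2.29e-05; 0 over all genes, 1 adjusted over the list alone; adjusted p of 0.541 with an estimated correlation). The proliferation list, higher on the average, was lower in these cells for 17 of 19 members (median -0.31; -0.45 and 0.085; camera adjusted p = 0.0374; 0 over all genes, 0 adjusted over the list alone; adjusted p of 0.541 with an estimated correlation). The remaining lists called higher were MHC class II (7 of 7 members, median 0.93, with 1.46 in run 1 and -0.12 in run 2), fatty acid oxidation (13 of 19, 0.14, with 0.33 and 0.028) and distal small intestine (4 of 6, 0.35, with 0.80 and -0.38). Without the run 1 cells of KO M2 these medians were 0.31, -0.035 and -0.16 and none of the 3 was called. That setting also ended the calls of absorption (0.0088), NRF2 targets (0.021), proliferation (-0.35) and ribosomal protein (-0.099) in these cells. Called lower were oxidative phosphorylation (41 of 49 members, median -0.27, with -0.53 and 0.073) and ribosomal protein (34 of 40, -0.23, with -0.65 and 0.11). In this order the camera adjusted p were 1.60e-07, 0.000930, 0.0430, 9.43e-05 and 9.43e-05, and 0.541, 0.599, 0.599, 0.737 and 0.737 with an estimated correlation. No member passed over all genes, and 4, 1, 2, 0 and 1 passed adjusted over the list alone. limma called 0 genes without the cells that carried Paneth transcripts, 0 in run 2 cells and 0 without either WT animal, and kept all 5 without either KO animal. Without the run 1 cells of KO M2 it called 1 gene, which was not among the 5.

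In cells annotated Enterocyte, the mature absorptive type, KO animals again had more antimicrobial transcripts, while absorption genes had lower values. Reg1, a secreted C-type lectin, rose from 1018 and 466 TPM in WT to 5596 and 4189 TPM in KO (2.81, SE 0.31; 3.52 in run 1 and 2.28 in run 2; limma Benjamini-Hochberg adjusted p = 0.0214). The unnamed gene 2210407C18Rik, chosen after its values were seen, also rose (1.69, SE 0.17; 3.99 and 0.13; limma Benjamini-Hochberg adjusted p = 0.0172), with both KO animals above both WT animals for each of these genes. The antimicrobial list was higher for 19 of 23 members (median 2.81; 3.62 and 1.36; camera adjusted p = 2.07e-10), 1 over all genes and 14 higher and 3 lower adjusted over the list alone, with an adjusted p of 0.510 with an estimated correlation. Lyz1 stood at 19.6 and 2.77 TPM in WT and 598 and 94.3 TPM in KO. In KO M1, 1 of 12 cells held 91.7% of the Paneth marker TPM. Enterocyte absorption genes were lower for 27 of 33 members (median -0.39; camera adjusted p = 1.57e-05), 0 over all genes and 3 adjusted over the list alone, with an adjusted p of 0.510 with an estimated correlation, but the median was 0.14 in run 1 and -0.16 in run 2. The apolipoprotein genes Apoa1 (8339 and 10487 TPM in WT, 4303 and 5856 in KO; -0.90, SE 0.18) and Apoc3 (-1.82, SE 0.35) had the smallest p in the list, though Apoc3 differed by 0.16 with log values averaged over cells. MHC class I genes were lower for 11 of 11 members (median -0.22, with 0.11 in run 1 and -0.34 in run 2). The ribosomal protein list, lower on the average, was called higher for 30 of 40 (median 0.12, with -0.81 and 0.57). For that list KO M1 lay above and KO M2 below both WT animals. Both lists had a camera adjusted p of 0.00872 (0.510 and 0.768 with an estimated correlation). In each, 0 members passed over all genes and 0 adjusted over the list alone. The remaining Enterocyte lists called lower were cholesterol synthesis (18 of 22 members, median -0.36, with 0.11 in run 1 and -0.74 in run 2), distal small intestine (6 of 7, -0.79, with 0.24 and -1.05), interferon response (12 of 16, -0.36, with 0.20 and -0.14). Oxidative phosphorylation was lower as well (36 of 49, -0.12, with -0.61 and 0.25, and -0.057 without the run 1 cells of KO M2, where it was not called). Goblet secretion was called higher (7 of 10, 1.94, with 2.42 and -0.49, and -0.71 without the run 1 cells of KO M2). In this order the camera adjusted p were 0.00872, 0.00872, 0.0237, 0.0307 and 0.0329 with the preset and 0.510, 0.598, 0.510, 0.768 and 0.676 with an estimated correlation. No member of these 5 passed over all genes, and 0, 2, 2, 0 and 5 passed adjusted over the list alone, the last as 3 higher and 2 lower. Papss2 (1.60), Ces2a (1.43), Ces1f (1.60) and Adh1 (1.28) were higher without passing, with 1.26 to 2.19 in run 1 and 1.14 to 1.81 in run 2. The peptidase gene Lap3 (-1.35), the bactericidal lectin gene Reg3g (-1.11), Igsf9 (-1.91) and Crip1 (-0.97) were lower without passing (-1.21 to -0.68 and -2.33 to -0.42). limma called 2 of 5854 genes (482 at an unadjusted p under 0.05), 0 in run 2 cells, 27 without the run 1 cells of KO M2, of which 1 was shared, 31 without WT M1 and 55 without KO M2.

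Goblet cells, which secrete mucus, had less Olfm4 in KO, a secreted glycoprotein gene that marks crypt base stem cells (292.9 and 321.4 TPM in WT, 67.4 and 48.8 in KO). Olfm4 fell by 2.40 (SE 0.31, limma Benjamini-Hochberg adjusted p = 0.0225, lower in both KO animals than in both WT animals), with -2.64 in run 1 and 0.61 in run 2. Genes of both energy metabolism and translation were lower: oxidative phosphorylation for 46 of 49 members (median -0.51; -0.52 in run 1 and -0.39 in run 2; camera adjusted p = 9.32e-19) and ribosomal protein for 40 of 40 (median -0.53; -0.49 and -0.36; camera adjusted p = 4.35e-21). Over all genes 0 members of either passed, 14 and 18 passed adjusted over the list alone, and the adjusted p was 0.867 for both with an estimated correlation. Ndufs6 differed by -1.28 (SE 0.29). In run 2 the list means were 8.19 and 8.40 in WT, 7.58 in KO M1 and 8.18 in KO M2, and for ribosomal protein 9.96, 10.40, 9.33 and 10.23. Neither list was called in run 2 cells alone (camera adjusted p = 0.164 and 0.279). Of the 11 run 2 Goblet cells of KO M1, 4 carried 42.4 to 44.8% Paneth marker TPM. Without the cells that carried Paneth transcripts the medians were -0.35 and -0.43, and both lists were still called. The antimicrobial list was higher for 18 of 27 members (median 1.26; -0.085 in run 1 and 3.42 in run 2; camera adjusted p = 0.000210), 0 over all genes and 6 adjusted over the list alone, with an adjusted p of 0.867 with an estimated correlation. Without passing, Defa5 (4.31), Itln1 (1.24), Stard13 (2.98) and the secreted phospholipase gene Pla2g2a (3.50) were higher (0.67 to 3.61 in run 1, 1.16 to 8.10 in run 2), and Rps27 (-2.09), the copper chaperone gene Atox1 (-1.53), the mucus-associated peptide gene Spink4 (-1.22) and Rps28 (-1.11) lower (-1.80 to -1.27 and -2.58 to -0.13). The Goblet antimicrobial list was not called without the run 1 cells of KO M2 (median 0.39, camera adjusted p = 0.0648). Its median was -0.56 without KO M1 and 0.31 without WT M2. By animal the list means were 7.86 and 6.13 in WT, 10.5 in KO M1 and 6.27 in KO M2, so only KO M1 lay above both WT animals. Goblet Itln1 differed by -0.049 without the cells that carried Paneth transcripts and by -0.73 with log values averaged over cells. The other Goblet lists called were MHC class II (5 of 6 members higher, median 0.80, with 1.72 in run 1 and -1.36 in run 2, and -0.031 without the run 1 cells of KO M2), proliferation (30 of 37 higher, 0.19, with 1.11 and -2.37) and epithelial inflammation (9 of 12 lower, -0.28, with -0.31 and 0.078). Their camera adjusted p were 0.0122, 0.0122 and 0.0437 with the preset and 0.867 with an estimated correlation. In each, 0 members passed over all genes and 0 adjusted over the list alone. limma called 1 of 6208 genes (6.07% of them at an unadjusted p under 0.05), 0 in run 1 cells, 5 in run 2 cells, 0 without WT M2, 25 without KO M1 and 20 without KO M2. With the animals regrouped as WT M1 and KO M1 against WT M2 and KO M2, it called 4 Goblet genes, more than between genotypes. Olfm4 was not called without WT M1 (-2.47, limma adjusted p = 0.0859).

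Part of the antimicrobial signal lay in few cells. The 9 Paneth markers took a median of 40.7% of TPM in cells annotated Paneth. In KO M1, 4 Goblet cells of run 2 carried 42.4 to 44.8%, together 92.6% of the Paneth marker TPM of that animal's 21 Goblet cells. Goblet markers took 6.06% in 1 of these 4 cells and 0.102, 0.194 and 0.215% in the others, against medians of 9.44% in 65 other Goblet cells and 0.200% in Paneth cells. A WT M1 Goblet cell of run 1 carried 22.9% Paneth and 14.4% Goblet marker TPM. Outside Goblet cells the highest shares in KO were 16.9% in an Enterocyte.prog.early cell, 19.5% in an Enterocyte.prog.late cell and 4.36% in an Enterocyte cell, and the highest in WT cells of these types was 1.34%. With the 9 cells above 3% left out, the antimicrobial median was 0.77 in Enterocyte.prog.late, 0.98 in Enterocyte and 0.083 in Goblet cells, where the list was no longer called (camera adjusted p = 0.890). No annotated type among the 6 other than Enterocyte had both KO animals' median cells above both WT animals' (0.0116 and 0.0121% in KO, 0.00503 and 0.000844% in WT Enterocyte cells).

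**Figure D4:**
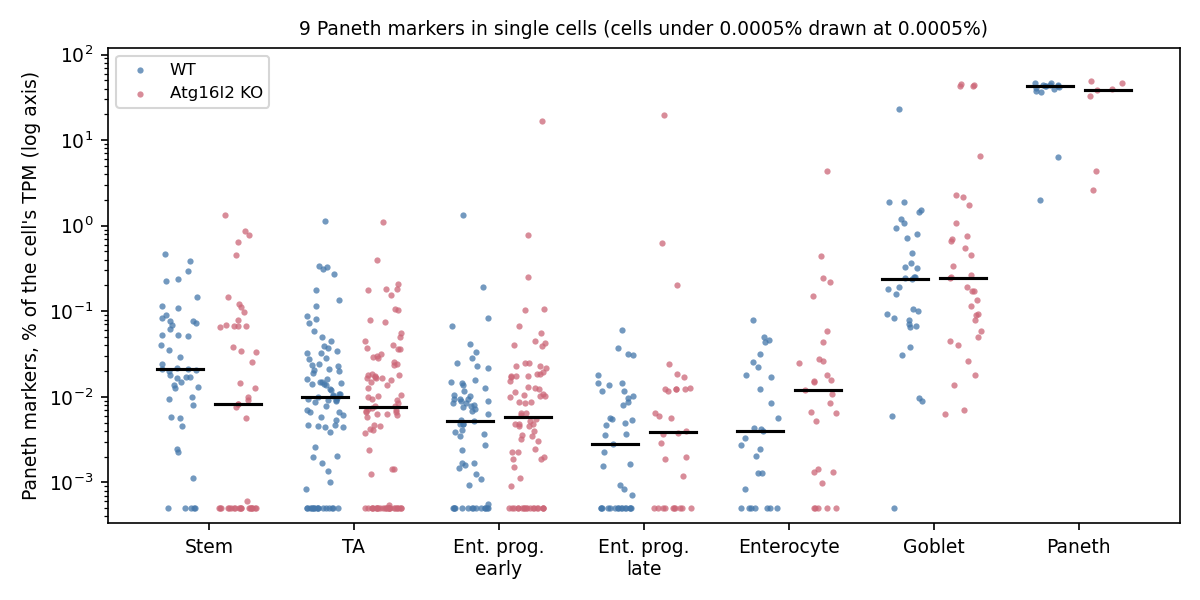
Share of each cell's TPM taken by 9 Paneth markers (vertical axis, %, log scale) in 7 annotated types, with 1 point per cell, blue for WT, red for KO and black lines for medians; shares under 0.0005% are drawn at that value. Outside the Paneth type, 4 KO Goblet cells lay at 42.4 to 44.8%.

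The last test asked for genes whose KO minus WT difference was not the same in the 6 cell types. Kcnn4, which encodes a calcium-activated potassium channel, was the 1 gene of 6714 that passed (limma moderated F = 25.5, Benjamini-Hochberg adjusted p = 0.00214). In WT, Kcnn4 was present up to Enterocyte.prog.late (94.5 and 118.4 TPM) and nearly absent from Enterocyte cells (0.508 and 0.138 TPM), whereas KO Enterocyte cells had 14.7 and 24.4 TPM. The difference was 3.93 in Enterocyte cells, against 0.07 in Stem, 0.27 in TA, 0.28 in Enterocyte.prog.early, -0.61 in Enterocyte.prog.late and 0.25 in Goblet cells. Kcnn4 was above 10 TPM in 10 of 29 KO Enterocyte cells and in 0 of 29 WT Enterocyte cells, where 2 were above 0. Within run 1 the KO animals stood at 3.52 and 19.8 TPM against 1.31 and 0.253 in WT, and within run 2 at 20.3 and 26.3 TPM against 0 and 0. The call ended with a pseudocount of 10 (limma adjusted p = 0.318), with log values averaged over cells (0.773), in run 1 (0.777) or run 2 cells alone (0.681), without WT M1 (0.161) and without WT M2 (0.312). The next genes by p, with limma adjusted p from 0.226 to 0.280, did not pass: Reg1 (-1.36 in Stem, 3.595 in Goblet), the potassium channel subunit gene Kcne3 (1.10 in Enterocyte, -1.05 in Goblet), Mid1 (2.55 in Enterocyte, -1.48 in Enterocyte.prog.early), Nif3l1 (2.18 in Enterocyte), Lap3 (-1.35 in Enterocyte), Dynlt1a (2.06 in Stem, -1.54 in Enterocyte) and Gpatch4 (2.36 in Enterocyte). The test counted 490 genes at an unadjusted p under 0.05 against 335.7 by chance.

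**Figure D5:**
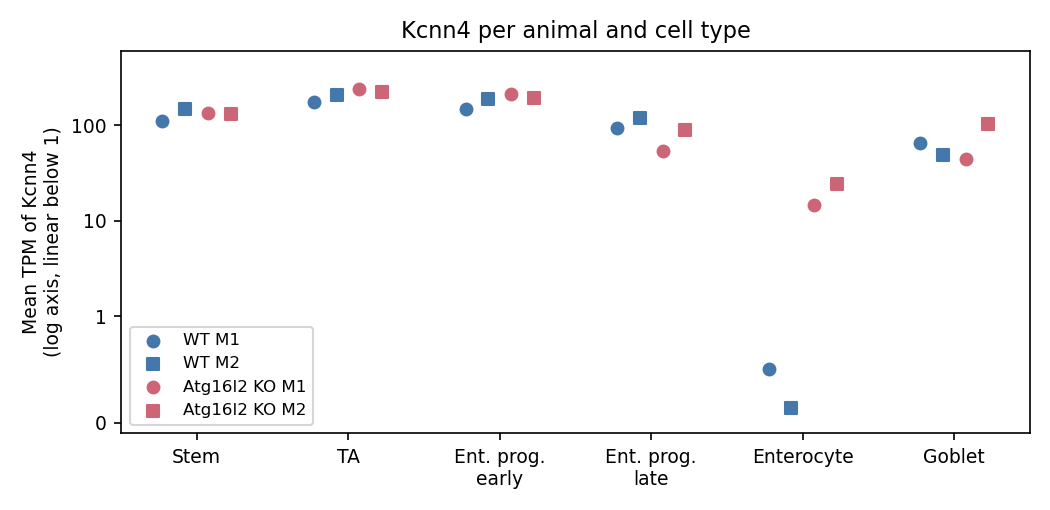
Mean TPM of Kcnn4 (vertical axis, log scale above 1 TPM and linear below) per animal in the 6 tested cell types, with circles for M1, squares for M2, blue for WT and red for KO. In Enterocyte cells the KO animals lay at 14.7 and 24.4 TPM and the WT animals at 0.508 and 0.138 TPM.

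Paneth, Enteroendocrine and Tuft cells numbered fewer than 10 in at least 1 animal and were described without a test. Paneth cells carried Lyz1 at 31771 and 42348 TPM in WT and 32284 and 5939 TPM in KO, and Defa24 at 162111 and 209943 against 225532 and 70109.2 TPM. Paneth marker shares were 4.41 and 2.64% in 2 of the 3 KO M2 cells annotated Paneth, 6.30 and 2.005% in 2 of the 6 WT M1 cells, and 32.5% or more in all others. Enteroendocrine cells carried the secretory granule gene Chga at 11835 and 17831 TPM in WT and 9978 and 9379 in KO. The hormone gene Gip stood at 87339.7 and 2841 TPM in WT and at 0 and 66.7 in KO, from 9, 3, 5 and 15 cells, and Cck at 7890.3 and 0 against 175.004 and 14511 TPM. Tuft cells carried the channel gene Trpm5 at 157.8 and 1527 TPM in WT and 1794 and 928 TPM in KO. The authors' annotation was described by fixed markers: 9 of 10 Stem, 10 of 10 Enterocyte, 7 of 8 Goblet, 8 of 9 Paneth, 11 of 11 Enteroendocrine and 9 of 9 Tuft markers had their highest mean in their own type, against 3 of 10 TA, 3 of 8 Enterocyte.prog.early and 0 of 8 Enterocyte.prog.late markers.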

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

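All but 1 of the tests weighed here were chosen only after the result was seen; the exception is the test of cell maturity for Kcnn4.

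Kcnn4 differed between genotypes in a way that was not the same in the 6 cell types (limma interaction, Benjamini-Hochberg adjusted p = 0.00214), being higher in KO cells annotated Enterocyte. One cell per animal as the source is argued against, because with the highest cell of each animal left out the Enterocyte difference minus the mean of the other types was still 3.64 (limma adjusted p = 0.0107). A different mix of the 2 runs is argued against as well, because both KO animals lay above both WT animals in 2 of 2 runs. Less mature cells among the KO cells annotated Enterocyte cannot be told apart from a change of Kcnn4 itself. Genes lost there in WT kept a median of 0.314% of their Enterocyte.prog.late level in WT cells and 12.5% in KO cells. For Kcnn4 these values were 0.303% and 27.4%. Only 4 genes qualified, which keeps the question open. They were also chosen for keeping at most 5% in these WT cells, so a higher KO value is partly fixed by the choice. The call ended in either run alone and without either WT animal.

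Another 3 contrasts were not tested as interactions. The MHC class I list lay above WT in TA and Enterocyte.prog.early and below it in Enterocyte cells (TA median minus Enterocyte median 0.62). Both KO animals also lay below WT in Goblet cells (median -0.40), where the list was not called. The antimicrobial list lay above WT in Stem, Enterocyte.prog.late and Enterocyte and below it in TA cells (3.31). The enterocyte absorption list lay above WT in Enterocyte.prog.early and Enterocyte.prog.late and below it in Enterocyte cells (0.69). Within runs the sign change of the absorption list was absent, with medians of 0.50, 0.60 and 0.14 in run 1 and -0.031, -0.087 and -0.16 in run 2 in the order named. That of the MHC class I list was absent in run 1 (0.33, 0.55 and 0.11), and without the run 1 cells of KO M2 its TA and Enterocyte.prog.early medians were 0.052 and 0.0010 and it was called in neither. The TA antimicrobial list was not called without KO M1 (median -0.075), the absorption list in Enterocyte.prog.late not without the run 1 cells of KO M2 (0.0088), and no list was called in any type with an estimated correlation. Whether these lists respond differently by cell type was not tested.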

How the results depend on the processing

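Tests of the alternatives marked as added were chosen only after the results were seen; the others were fixed beforehand.

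A value stayed the same if its sign and, for genes and lists, its call were those of the main analysis. Its size could differ, and for uncalled genes the same call is no call. Of 2301 values for named genes, 1958 stayed the same, 160 were stronger, 28 reversed and the others weaker. For 1194 list values these counts were 917, 1 and 65. Of 83 shares, 66 stayed the same and 17 reversed. Of 240 for main results, 130 stayed the same, 2 were stronger and 108 moved. No cause was tested. The 2000-gene filter removed no cell, and Atg16l2 has no value under the 50 TPM filter.

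Limma call counts by setting, Benjamini-Hochberg adjusted, follow. Without the filter on low values: 11 lists, 40 interaction genes, 0 in TA, Enterocyte.prog.late, Enterocyte and Goblet, and the distal list in Enterocyte.prog.late at -0.27. With log values averaged over cells: 4 lists, 9 Goblet genes, and 0 in Enterocyte.prog.late, Enterocyte and the interaction; Atg16l1 differed by 0.10, Apoc3 in Enterocyte by 0.16, Itln1 in Goblet by -0.73 the Stem antimicrobial list by -0.053, the Stem stem cell list by 0.075 and the Enterocyte goblet secretion list by -0.12. With quantile normalization: 1 in the average, 8 in Enterocyte.prog.late, 11 in Enterocyte, 0 in TA and Goblet, and Nnt at -0.023. Rescaled without ribosomal protein genes: 0 in TA, and Nnt at -0.0094. With at least 50 TPM: 0 in TA and Enterocyte.prog.late, 8 in Enterocyte, 2 in Goblet, and the Stem stem cell list at 0.016. Without a trend in eBayes: 0 in TA, Enterocyte.prog.late, Enterocyte and Goblet. With a pseudocount of 10: 1 in Enterocyte.prog.late, 5 in Enterocyte and 0 in the interaction; with 0.1, 7 in the interaction. With camera and an estimated correlation: 0 lists.

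In run 1 cells: 2 in TA, 1 each in Enterocyte.prog.late and Enterocyte (neither shared), and 0 in Goblet and the interaction. Atg16l1 stood at 0.18, Nnt at -0.20, the Enterocyte absorption list at 0.089, the Enterocyte MHC class I list at 0.11, the Enterocyte ribosomal protein list at -0.81, the Enterocyte interferon, distal and cholesterol lists at 0.20, 0.32 and 0.11, the Stem antimicrobial list at -0.0080, the Stem stem cell list at 0.28 and the Goblet antimicrobial list at -0.091. The low-value filter was applied within the run here, so a list can hold other members than in the report, whose run medians (0.14 for Enterocyte absorption and -0.085 for Goblet antimicrobial) keep the members tested over both runs. In run 2 cells: 5 in the average, 1 in Stem, 5 in Goblet, and 0 in TA, Enterocyte.prog.late and Enterocyte. There Rps27 stood at 0.32 in the average, 2.43 in Stem, 4.11 in TA and 0.95 in Enterocyte.prog.early. Bola2 was 0.26, H2-Aa -0.021, Uqcr11 0.14, Rpl38 0.24, Rn4.5s in Stem 1.42, Hist1h2ap in TA 2.07, Slirp in TA 0.40 and Olfm4 in Goblet 0.61. The run 2 list medians were -0.055 for MHC class II, -0.28 for proliferation, 0.0996 for ribosomal protein and 0.10 for it in TA, -0.062 for absorption and 0.12 for proliferation in Enterocyte.prog.late, and in Stem cells -0.039 for MHC class II, 0.091 for oxidative phosphorylation and 0.024 for ribosomal protein. In Enterocyte.prog.early cells they were 0.0089 for oxidative phosphorylation, 0.16 for ribosomal protein and -0.031 for absorption, and in Enterocyte.prog.late cells -0.12 for MHC class II, 0.073 for oxidative phosphorylation and 0.11 for ribosomal protein. Oxidative phosphorylation stood at 0.25 in Enterocyte cells, and in Goblet cells MHC class II stood at -1.36, epithelial inflammation at 0.078 and proliferation at -2.37. Shares in run 2 differed by 1.92 points for Stem, -1.22 for TA, 2.24 for Enterocyte, 2.04 for Goblet, -1.25 for Enteroendocrine and -0.65 for Tuft cells.

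With the 8 combinations of run and animal as units, by either model: 1 in the average, 1 in TA, and 0 in Enterocyte.prog.late, Enterocyte and Goblet. Atg16l2 passed there (-1.59, limma adjusted p = 0.0175 with duplicateCorrelation and 0.0258 as 8 animals), Nnt stood at -0.0040, Rps27 in TA at 0.62 NRF2 targets in Enterocyte.prog.late at -0.028 the Enterocyte ribosomal protein list at -0.11, the Stem stem cell list at 0.075 and the Goblet proliferation list at -0.63. With the replicate block the calls were 2 in the average, 6 in Stem, 10 in TA, 11 in Enterocyte.prog.late, 26 in Enterocyte and 48 in Goblet, but the numbers do not pair (deviation correlation -0.133 in the average). The crossed pairing, added, gave 44 calls in the average.

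Added settings: with the length trend removed, 3 in the average, 9 in Enterocyte.prog.late, 7 in Enterocyte, 0 in TA and Goblet, Nnt at -0.0196 and the TA antimicrobial list at 0.030. With cells of at least 5000 genes, 4 in the average, 1 in Stem, 11 in Enterocyte.prog.late, 5 in Enterocyte, 2 in the interaction, 0 in TA and Goblet, and the Stem stem cell list at 0.039. With the highest cell left out, 3 in the interaction, 0 in TA, Enterocyte.prog.late, Enterocyte and Goblet, the Stem stem cell list at 0.013 and the distal list in Enterocyte.prog.late at -0.17. Without the run 1 cells of KO M2, 1 in TA, 1 in Enterocyte.prog.late, 27 in Enterocyte, 0 in Goblet, 4 in the interaction, and the Stem MHC class II list at -0.097. The distal and fatty acid oxidation lists in Enterocyte.prog.late then stood at -0.16 and -0.035, goblet secretion in Enterocyte at -0.71, and MHC class II and proliferation in Goblet at -0.031 and -0.0060. With 3 Goblet cells of Paneth profile counted as Paneth, the Paneth share differed by -1.56 points and the Goblet share by -1.11. Without cells carrying Paneth transcripts, 0 in Enterocyte.prog.late, 6 in Enterocyte, Itln1 in Goblet at -0.049 and the antimicrobial list in Enterocyte.prog.early at -0.079.

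Leaving out 1 animal treats the lone animal as if it varied like the other group. Calls then ranged from 0 to 19 in the average (19 without KO M2), 4 to 9 lists, 0 to 13 in Stem (13 without KO M1), 0 (without WT M2) to 2.3e+02 in TA (without KO M1), 0 to 6 in Enterocyte.prog.early, 0 (without either WT animal) to 1.4e+02 in Enterocyte.prog.late (without KO M1), 5 to 55 in Enterocyte, 0 (without WT M2) to 25 in Goblet and 0 (without WT M1) to 3 in the interaction. Atg16l1 ranged from -0.23 to 0.0045, Nnt from -0.10 to 0.16, the Goblet antimicrobial list from -0.56 (without KO M1) to 3.35, the Stem MHC class II list from -0.28 to 0.82 and the Enterocyte ribosomal protein list from -0.0022 to 0.28. The Stem stem cell list ranged from -0.13 to 0.071, the antimicrobial list in Enterocyte.prog.early from -0.31 to 2.28 and the distal list in Enterocyte.prog.late from -0.063 to 0.98. Goblet secretion in Enterocyte ranged from -0.60 to 2.09, oxidative phosphorylation in Enterocyte from -0.26 to 0.010, and MHC class II and proliferation in Goblet from -0.044 to 1.57 and from -0.11 to 0.57. Shares ranged from -4.05 to 2.23 points for Stem, -2.26 to 4.15 for TA, -7.02 to 0.106 for Enterocyte.prog.late, -2.23 to 1.90 for Enterocyte, -2.95 to 2.48 for Goblet, -0.67 to 5.25 for Enteroendocrine and -0.028 to 0.574 for Tuft cells.

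Several lists kept their direction but were no longer called by camera, here with their median. With the run 1 cells of KO M2 left out these were on the average MHC class II (0.065) and proliferation (0.023), in Stem inflammation (-0.24), in TA MHC class II (0.20) and MHC class I (0.052), and in Enterocyte.prog.early MHC class II (0.51), ribosomal protein (-0.074) and MHC class I (0.0010). The same setting ended the call in Enterocyte.prog.late absorption (0.0088), NRF2 targets (0.021), proliferation (-0.35), MHC class II (0.31) and ribosomal protein (-0.099), in Enterocyte oxidative phosphorylation (-0.057), and in Goblet antimicrobial (0.39) and inflammation (-0.35). With the highest cell left out they were on the average stem cell (0.29), in Stem antimicrobial (0.27), MHC class II (0.30) and inflammation (-0.20), and in Enterocyte.prog.early MHC class I (0.23) and antimicrobial (0.34). Without cells carrying Paneth transcripts they were in Enterocyte.prog.early MHC class I (0.27), in Enterocyte goblet secretion (1.51), and in Goblet antimicrobial (0.083), MHC class II (0.85) and inflammation (-0.15). With the 8 combinations as animals they were on the average proliferation (0.085), in Stem antimicrobial (0.43) and proliferation (0.19), in TA antimicrobial (-0.11), and in Enterocyte.prog.early MHC class I (0.28) and antimicrobial (0.44). That setting also ended the call in Enterocyte.prog.late proliferation (-0.14) and distal (0.032), in Enterocyte absorption (-0.059), MHC class I (-0.089), interferon (-0.17), distal (-0.41) and goblet secretion (1.14), and in Goblet MHC class II (0.24) and inflammation (-0.055). With log values averaged over cells they were on the average antimicrobial (0.27), stem cell (0.20) and proliferation (0.080), in Stem MHC class II (0.43), proliferation (0.38) and inflammation (-0.37), and in Enterocyte.prog.early MHC class I (0.13) and antimicrobial (0.042). Averaged log values also ended the call in Enterocyte.prog.late antimicrobial (0.34), NRF2 targets (0.18), proliferation (-0.35) and distal (0.059), in Enterocyte absorption (-0.044) and interferon (-0.31), and in Goblet inflammation (-0.48) and proliferation (0.077). Leaving out 1 animal ended the call, in at least 1 of the 4 cases, with ranges of medians on the average MHC class II (0.39 to 1.202), stem cell (0.18 to 0.37), proliferation (0.14 to 0.27) and fatty acid oxidation (0.092 to 0.29), in Stem proliferation (0.0030 to 0.50), fatty acid oxidation (0.075 to 0.46) and inflammation (-0.29 to -0.13), in TA MHC class I (0.25 to 0.45) and antimicrobial (-0.59 to -0.075), and in Enterocyte.prog.early MHC class I (0.14 to 0.31) and fatty acid oxidation (0.14 to 0.31). The same held in Enterocyte.prog.late NRF2 targets (0.020 to 0.31), proliferation (-0.46 to -0.25), oxidative phosphorylation (-0.49 to -0.052), fatty acid oxidation (0.014 to 0.41) and ribosomal protein (-0.37 to -0.048), in Enterocyte MHC class I (-0.44 to -0.12), interferon (-0.53 to -0.24), distal (-1.13 to -0.41) and cholesterol (-0.64 to -0.29), and in Goblet inflammation (-0.41 to -0.074). Rescaled without ribosomal protein genes, the calls ended in Stem MHC class II (0.28), in TA MHC class I (0.27), in Enterocyte.prog.early MHC class I (0.23), and in Enterocyte.prog.late proliferation (-0.33) and distal (0.30). Without a trend in eBayes they ended in Stem MHC class II (0.35), in Enterocyte.prog.early MHC class I (0.27), antimicrobial (0.61) and fatty acid oxidation (0.22), and in Enterocyte.prog.late proliferation (-0.31) and distal (0.35). They also ended there in Enterocyte MHC class I (-0.22), ribosomal protein (0.12), interferon (-0.36), distal (-0.79), goblet secretion (1.94) and oxidative phosphorylation (-0.12), and in Goblet MHC class II (0.80), inflammation (-0.28) and proliferation (0.19). With quantile normalization they ended in Stem inflammation (-0.28), in Enterocyte.prog.late distal (0.39), in Enterocyte goblet secretion (1.95) and oxidative phosphorylation (-0.057), and in Goblet MHC class II (0.84) and inflammation (-0.25). With at least 50 TPM they ended on the average stem cell (0.22), in Stem MHC class II (0.28) and inflammation (-0.19), and in TA antimicrobial (-0.37). That filter also ended the call in Enterocyte.prog.late proliferation (-0.31) and distal (0.28), and in Enterocyte interferon (-0.33), goblet secretion (1.08), oxidative phosphorylation (-0.12) and cholesterol (-0.25). Without the filter on low values they ended in Stem MHC class II (0.37) and inflammation (-0.20), in TA MHC class I (0.32), and in Enterocyte.prog.early MHC class I (0.28) and antimicrobial (0.56). Dropping that filter also ended the call in Enterocyte.prog.late NRF2 targets (0.019) and proliferation (-0.25), in Enterocyte ribosomal protein (0.12) and distal (-0.43), and in Goblet antimicrobial (0.87), MHC class II (0.67), inflammation (-0.25) and proliferation (0.22). With cells of at least 5000 genes they ended in Stem inflammation (-0.38), in Enterocyte MHC class I (-0.16), ribosomal protein (0.048) and interferon (-0.33), and in Goblet antimicrobial (0.086) and MHC class II (1.01). With the length trend removed they ended in Enterocyte.prog.late oxidative phosphorylation (-0.086) and ribosomal protein (-0.059), and in Enterocyte goblet secretion (2.07) and oxidative phosphorylation (-0.0066).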

Other observations

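The tests weighed in this part were all chosen only after the results were seen.

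Among WT cells Atg16l2 was seen most often in Enteroendocrine (4 of 12), Stem (11 of 49) and TA (16 of 85) cells, the 4 Enteroendocrine cells all being from WT M1 (4 of 9, against 0 of 3 in WT M2), and Kcnn4 was highest in TA cells (173.06 and 207.98 TPM in WT, 238.04 and 220.3 TPM in KO). Neither distribution was compared by a test.

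On the average of 6 cell types, oxidative phosphorylation and ribosomal protein genes were lower in KO, with Rps27 as the largest single difference. In Enterocyte cells the ribosomal protein median was 0.12, with KO M1 above and KO M2 below both WT animals. A technical difference between the WT and KO libraries of run 1 could account for the average lists, whose run 2 medians were -0.023 and 0.0996. In Goblet cells, with run 2 medians of -0.39 and -0.36, it cannot be told apart from a genotype effect because of the spread between animals (SE 0.32 and 0.50). KO M1 had the lowest run 2 Goblet means (7.58 and 9.33), and 4 of its 11 run 2 Goblet cells carried 42.4 to 44.8% Paneth marker TPM. How far these cells lowered the means was not tested. For Rps27 a run 1 difference cannot be told apart from other causes. Run 2 gave -6.94 (SE 0.97) in Enterocyte.prog.late, -2.58 (SE 2.37) in Goblet and 2.43 (SE 0.32) in Stem cells. The other types lay above WT, and the average was 0.32. With the transcript length trend removed, Rps27 still differed by -2.55. The ribosomal protein list was still called (median -0.059, camera adjusted p = 0.00225, difference of list means -0.13, SE 0.038). So was oxidative phosphorylation, with a wide spread between animals (median -0.079, camera adjusted p = 2.42e-06, difference of list means -0.15, SE 0.075). Length as the whole cause cannot be told apart, as the longest annotated transcript need not be the one present. A genotype effect of the same size in both runs is argued against for Rps27 (run 2 minus run 1 difference 5.30, SE 0.91), while for the lists (0.57, SE 0.42, and 0.85, SE 0.50) it cannot be told apart from a run 1 difference because of the spread between animals, and no other biological explanation was tested.

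Paneth transcripts were higher in KO cells of some other annotated types, but not in TA cells, where the mean marker shares were 0.0254 and 0.0564% in KO and 0.0331 and 0.0627% in WT, nor in Goblet cells of KO M2 (0.381%, against 2.16 and 0.459% in WT), and Enterocyte.prog.early cells of KO M2 (0.0169%) lay between the WT animals (0.0563 and 0.0114%). A rise in most KO cells is argued against outside the Enterocyte type, because both KO animals' median cell lay above both WT animals' in only 1 of 6 types, Enterocyte. Whether the cells with much Paneth RNA are doublets, carry ambient RNA, are Paneth cells under another label or are cells between types was not tested, and no biological explanation was tested.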
